A study of Arabidopsis thaliana with 8 samples.

How the data were processed

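The series holds 8 2-colour long-oligonucleotide microarrays of Arabidopsis thaliana. Each array compared RNA from embryos of the cross Q0990 x bdl with RNA from embryos of the cross Q0990 x Col-0, with 4 arrays at day 3 and 4 at day 6. Per the labels' protocols, Q0990 was the seed parent in both crosses, embryos were isolated 3 or 6 days after pollination, and total RNA was amplified and coupled to Cy3 or Cy5. The series text counts the same days from fertilization. It names 4 biological replicates for each experiment, and the labels put the Q0990 x bdl RNA in Cy5 on 2 arrays and in Cy3 on 2 arrays of each day.

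The authors deposited 1 intensity per channel and spot, with no background column and no quality flags. Image software, background method and normalization were not given in the sources used here, and the series text says that the scanner's own output was lost. The deposited intensities looked already processed. The median log2 ratio lay between -0.0354 and 0.0338 in every decile of brightness above the dimmest, blank spots had median intensities between 7.46 and 25.1, and all 8 arrays held values over the 16-bit ceiling of 65535 in at least 1 channel. These values were therefore taken as background-subtracted and balanced between channels. The deposited series table holds log2 ratios of Q0990 x bdl over Q0990 x Col-0, and at least 99.9% of its values on each array equalled the log2 ratio of 1 spot's deposited intensities to 6 decimals. Its column medians lay between -0.0101 and 0.0195. Its rows carry no names used here, so it served only for counts of changed reporters.

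The arrays carried 30274 to 30277 spots, of which 2672 were controls. Among the gene spots, 22325 had values on each day 3 array and 26041 or 26042 on each day 6 array. The missing gene spots were the same 5277 on all 4 day 3 arrays, and 1563 were missing on all 4 day 6 arrays. 1 cell of day 6 replicate 1 held a letter and was set missing. There were 27462 different reporters (probes), 27387 of them with 1 gene code and 75 microRNA reporters without one, and they covered 24648 genes. Gene symbols came from the TAIR10.1 reference gene table, which held 19599 (99.4%) of the tested gene codes. Other genes, and genes without a symbol there, keep the code in the files. No genome build is used and no coordinate is given.

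An offset of 50 was added to each intensity, log2 ratios were formed as Q0990 x bdl over Q0990 x Col-0, and each array was normalized by loess (span 0.3, 4 iterations, control spots given no weight). The design fixed before the data were examined had assumed scanner files with a background column and flags. Without them, normexp background correction with offset 50 became an added alternative, and the filter was set on blank spots. A reporter was kept if its intensity exceeded the 95th percentile of the blank spots of that channel and array (1743 blank spots per array) in at least 4 of the 16 channel signals. This choice followed from the file structure and preceded any test. It kept 22002 reporters (80.1%) of 19720 genes, 1415 of which had more than 1 kept reporter. The 95th percentile of the blank spots was 27.3 to 87.5 on the day 3 arrays and 68.4 to 308 on the day 6 arrays. It also differed between channels, as on day 6 replicate 2 (80.9 for Q0990 x bdl, 213 for Q0990 x Col-0). Counts of arrays on which a gene exceeded the blank spots are therefore not strictly comparable between days or crosses. Spots of a reporter were averaged, and so were the reporters of a gene. Among called genes with several reporters, the reporters had mean ratios of opposite sign for 47 of 596 genes on day 3 and for 104 of 539 on day 6. Of the genes, 18834 were measured on all 8 arrays, 253 on day 3 only and 633 on day 6 only.

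limma 3.58.1 in R 4.3.3 fitted the log2 ratios of all 8 arrays with a day 3 effect, a day 6 effect and a dye effect (lmFit, eBayes), with at least 3 arrays required per day. Adjusted p-values are Benjamini-Hochberg values over all genes of a comparison, and a gene was called at an adjusted p under 0.05. The difference between days was the day 6 effect minus the day 3 effect in the same fit. The change of Q0990 x Col-0 embryos between days used limma's separate-channel model (Aquantile normalization, intraspot correlation 0.946, statmod 1.5.0). No array held both days, so this comparison runs between arrays. A fold printed as "at least" was used where a gene was not above the blank spots on any array of the dimmer side. It sets the brighter side's mean against the higher of the gene's own signal and the lowest signal above the blank spots on each array. All p-values rest on 4 arrays per day, whose number limits the precision. Array ratios correlated across genes at r = 0.575 to 0.779 among day 3 arrays and 0.732 to 0.868 among day 6 arrays, and no pair of arrays shared identical ratios.

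A set of 19 gene lists with 358 genes was fixed from textbook knowledge before the data were examined. They cover Aux/IAA genes other than BDL, GH3 and LBD genes, auxin response factors, auxin transport and synthesis, MONOPTEROS targets and vascular initiation, vascular tissue, ground tissue, root pole, shoot apex and cotyledon, epidermis, suspensor and zygote, seed maturation and storage, endosperm, seed coat, cell cycle and DNA replication, cytokinin response, photosynthesis, heat shock, and touch and wounding. Endosperm and seed coat genes mark the other seed tissues that isolated embryos can carry. Lists were tested with limma's camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, with adjustment over the lists of a comparison. These tests used the members measured on both days, while counts and medians cover all members measured on the day in question. The fry test asks whether a list's genes move on balance in 1 direction and does not compare the list with other genes. For the Col-0 comparison the list tests used the Col channel alone. The rule for named genes was also fixed beforehand: BDL, the 8 largest rises and 8 largest falls on each day among genes called with the same sign on all 4 arrays, the 6 largest in each direction for the other comparisons, and up to 4 members with the smallest p from each list that is described.

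The gene tests and the list tests were tried on simulated gene values, drawn at random with the spread of each real gene. The offset, loess, blank-spot filter and averaging of reporters were not part of these simulations. Of 200 genes changed 1.5-fold, 82.5% were recovered on day 3 and 82.0% on day 6, with 5.2% and 5.7% of calls false. At 2-fold, 95.5% and 94.5% were recovered, with 4.0% and 8.3% of calls false, and at 1.2-fold none was. These simulations changed 200 of 18834 genes on each day, far fewer than were called in the real data (8032 on day 3, 6939 on day 6). The adjusted p threshold is easier to pass where more genes change. The rates, also that at 1.2-fold, therefore do not carry over to the real calls. The difference between days recovered 66.7% of genes changed 1.5-fold and 92.0% of those changed 2-fold. The separate-channel fit recovered 7.5% of genes changed 2-fold, with 40.0% of its 25 calls false, and 81.5% of those changed 4-fold and 97.5% of those changed 8-fold, with 11.4% and 8.5% of calls false. Its smaller calls are therefore less certain than its larger ones. Of 380 list tests without a change, 5.0% had p under 0.05. The simulated genes varied independently of each other, so this rate does not cover lists with correlated members.

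Alternatives planned beforehand were no background correction, an offset of 10, median centring, scale or quantile normalization, the series table, no filter and a strict filter, reporters as units, the brightest reporter per gene, other dye terms, each day alone, a variance trend, the replicate number as a block, a 1.5-fold threshold, the Col channel alone and the omission of each array. Added after the data were seen were normexp and a dye orientation read from the values. No slide or scan batch was given. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.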

Results

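Transcript levels were compared between Arabidopsis embryos of 2 crosses that shared the seed parent Q0990, a GAL4 enhancer trap line. The pollen parent was either bdl, the source of a stabilized form of the Aux/IAA repressor BODENLOS (BDL, IAA12), or the wild type Col-0. BDL binds and represses the auxin response factor MONOPTEROS (ARF5), which acts in embryo patterning. Both crosses were hybridized together on each of 8 arrays, 4 with embryos of day 3 and 4 with embryos of day 6, and each array came from a separate biological replicate according to the series text. Median intensities per channel were 336 to 524 on the day 3 arrays and 225 to 451 on the day 6 arrays. Ratios below are Q0990 x bdl over Q0990 x Col-0, as log2 values with the SD over 4 arrays where one is given.

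The BDL transcript itself was higher in the Q0990 x bdl embryos on both days. It was raised 1.82-fold on day 3 (log2 0.86 ± 0.0946 SD, n = 4, adjusted p = 2.67e-05) and 2.03-fold on day 6 (log2 1.02 ± 0.0916 SD, n = 4, adjusted p = 1.42e-05), on 4 of 4 arrays each time. The day 6 effect exceeded that of day 3 by 0.16, which did not pass the test of the difference (adjusted p = 0.141, 95% interval -0.0219 to 0.343). Of the 3 BDL reporters, the 2 bright ones gave log2 ratios of 1.09 and 1.34 on day 3 and 1.07 and 1.44 on day 6. The dim one gave 0.16 and 0.57. The arrays do not separate the introduced form from the endogenous transcript.

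On day 3, MONOPTEROS targets, vascular initiation genes and genes of the embryo's organ primordia were lower in Q0990 x bdl. Photosynthesis, endosperm and seed coat genes were higher. The largest falls were those of ASL5, a LATERAL ORGAN BOUNDARIES domain gene (5.92-fold lower, log2 -2.56 ± 0.352 SD, adjusted p = 9.75e-05), and of TMO7, a small bHLH gene that MONOPTEROS activates (4.13-fold lower, log2 -2.05 ± 0.312 SD, adjusted p = 3.22e-05). SOK1, a polarity gene, was 4.03-fold lower (log2 -2.01 ± 0.263 SD), and WOX5, which marks the root stem cell niche, was 3.94-fold lower (log2 -1.98 ± 0.170 SD). In the Q0990 x bdl channel, TMO7 exceeded the blank spots on 1 of 4 arrays, SOK1 on 2 and WOX5 on 3. AT1G29270, of unknown function, was 3.89-fold lower (log2 -1.96). ZW9, which encodes a MATH domain protein, was 3.46-fold lower (log2 -1.79), RGF8, a root growth factor peptide gene, 2.99-fold lower (log2 -1.58), and SAG13 2.91-fold lower (log2 -1.54).

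The largest rises on day 3 were those of SESA3 and SESA2, which encode seed storage albumins, and of several genes of unknown function. SESA3 was 14.1-fold higher (log2 3.82 ± 0.202 SD, n = 4, adjusted p = 3.19e-07) and SESA2 6.07-fold higher (log2 2.60 ± 0.379 SD, adjusted p = 1.14e-05). AT1G62080, AT1G62000, AT1G62210 and AT1G62060, which have close gene codes, were 8.36-fold, 8.08-fold, 7.06-fold and 4.91-fold higher. AT4G22440 was 6.67-fold higher (log2 2.74) and AT1G53285 4.61-fold higher. The Q0990 x Col-0 signals of AT1G62080, AT4G22440, SESA2 and AT1G62060 exceeded the blank spots on 3 of 4 arrays. All 16 of these rises and falls had the same sign on 4 of 4 arrays.

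Of 15 measured MONOPTEROS targets and vascular initiation genes, 11 fell on day 3 and none rose (12 fell adjusted over the list alone). The list median was -0.65 (camera adjusted p = 3.43e-07, and adjusted p = 0.0460 with an estimated correlation). Besides TMO7 and SOK1, LOG3, a cytokinin activating enzyme gene, fell 2.53-fold (log2 -1.34) and DOF5.8, a vascular transcription factor gene, 1.78-fold (log2 -0.83). Among 13 vascular tissue genes, 6 fell and none rose, the same adjusted over the list alone (median -0.17, or -0.15 with 1 member at its bound; camera adjusted p = 0.00207, but adjusted p = 0.0676 with an estimated correlation). AHP6, a cytokinin signalling inhibitor, was 1.71-fold lower and PHV, an HD-ZIP gene, 1.68-fold lower. Of 8 root pole genes, 4 fell, the same adjusted over the list alone (median -0.18, camera adjusted p = 0.0641). They included WOX5 and the stem cell regulator PLT2, which was 1.57-fold lower (log2 -0.65 ± 0.241 SD), and the list did not pass. In the ground tissue list 3 of 8 fell, the same adjusted over the list alone (camera adjusted p = 0.0914). On the same arrays the endosperm list had a median of 0.57 and the seed coat list one of 0.48.

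Shoot apex and cotyledon genes fell too, 10 of 13 with none higher (11 adjusted over the list alone; median -0.42, camera adjusted p = 1.09e-05, and adjusted p = 0.0256 with an estimated correlation). The cotyledon boundary gene CUC3 was 2.19-fold lower (log2 -1.13 ± 0.172 SD) and the organ polarity gene FIL 1.97-fold lower (log2 -0.98 ± 0.114 SD). Of 14 epidermis genes, 8 fell and 1 rose, the same adjusted over the list alone (median -0.22, camera adjusted p = 0.02499, but adjusted p = 0.0878 with an estimated correlation). PDF1 was 1.78-fold lower, and HDG2, a homeodomain gene, went the other way at 1.74-fold higher. Cell cycle and DNA replication genes fell in 27 of 35 cases with none higher, the same adjusted over the list alone (median -0.33, camera adjusted p = 4.98e-09, and adjusted p = 0.0256 with an estimated correlation). The cyclin gene CYCA1;1 was 1.75-fold lower and the mitotic kinase gene AUR1 1.57-fold lower. The endosperm and seed coat medians of 0.57 and 0.48 come from the same arrays as these falls.

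Hormone lists were mixed on day 3. Of 19 auxin transport and synthesis genes, 12 fell and 3 rose (13 and 3 adjusted over the list alone; median -0.34, camera adjusted p = 0.00149, but adjusted p = 0.0749 with an estimated correlation). The kinase gene PID, which directs PIN polarity, fell (log2 -1.07 ± 0.0511 SD), as did the auxin synthesis gene YUC4 (log2 -0.77 ± 0.0767 SD). Of 17 cytokinin response genes, 9 fell and 3 rose, the same adjusted over the list alone (median -0.32, camera adjusted p = 0.0162 over the 16 measured on both days, but adjusted p = 0.0749 with an estimated correlation). The response regulators ARR3 and ARR4 were 1.71-fold and 1.38-fold lower. Aux/IAA genes other than BDL moved both ways, 9 up and 3 down of 20 (9 and 4 adjusted over the list alone; median 0.07, camera adjusted p = 0.450). IAA30 was 2.23-fold lower and IAA16 1.79-fold higher. Auxin response factors had 7 of 15 lower and 3 higher (8 and 3 adjusted over the list alone; camera adjusted p = 0.142). GH3 and LBD genes had 2 of 8 lower and none higher, the same adjusted over the list alone (camera adjusted p = 0.450). These lists, too, were measured beside endosperm and seed coat medians of 0.57 and 0.48.

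Markers of the other seed tissues were higher on the same arrays on which the embryo lists were lower. Of 13 endosperm genes, 10 rose and none fell (10 up and 2 down adjusted over the list alone; median 0.57, camera adjusted p = 0.00149 over the 12 measured on both days, and adjusted p = 0.0460 with an estimated correlation). AGL36, an endosperm MADS gene, was 1.89-fold higher and ZOU, an endosperm bHLH gene, 1.72-fold higher. Of 25 seed coat genes, 17 rose and 1 fell, the same adjusted over the list alone (median 0.48, camera adjusted p = 4.04e-05, and adjusted p = 0.0256 with an estimated correlation). The flavonoid genes F3H and TT7 were 1.65-fold and 1.44-fold higher. Photosynthesis genes rose in 29 of 35 cases with 1 lower, the same adjusted over the list alone (median 0.46, camera adjusted p = 2.95e-10, and adjusted p = 0.0256 with an estimated correlation), with the Rubisco subunit genes RBCS2B and RBCS3B 2.39-fold and 1.54-fold higher. Seed maturation and storage genes had 5 of 19 higher and 4 lower, the same adjusted over the list alone. Their median was 0.01 and their mean 0.32 (camera adjusted p = 0.511). Of the suspensor and zygote list 1 of 3 was lower (camera adjusted p = 0.891), of heat shock genes 3 of 5 were higher (camera adjusted p = 0.251), and of touch and wounding genes 3 of 10 were lower (camera adjusted p = 0.347). Each of these 3 counts was the same adjusted over the list alone.

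**Figure D1:**
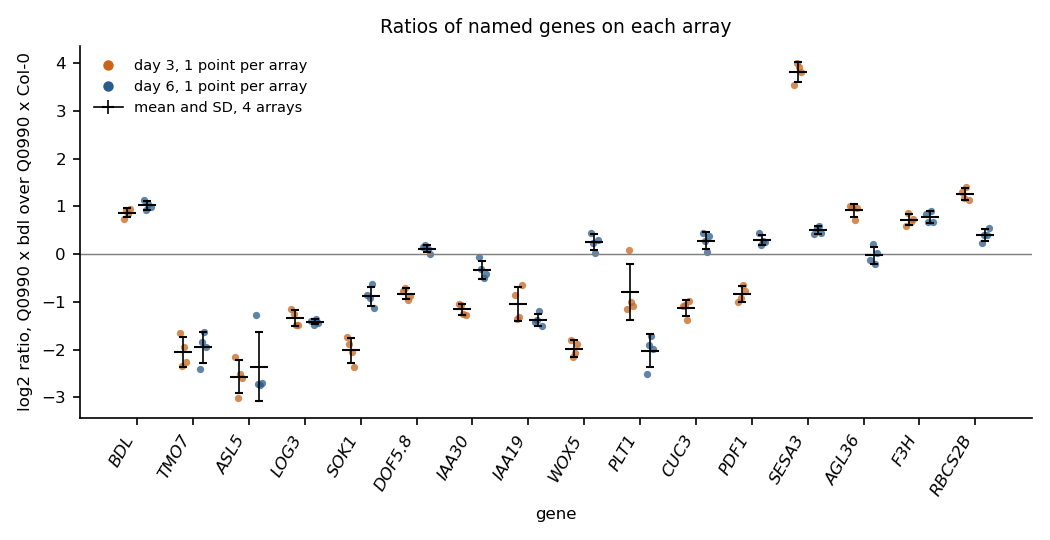
Log2 ratio of Q0990 x bdl over Q0990 x Col-0 (vertical axis) for 16 named genes (horizontal axis), with 1 point per array for day 3 and day 6, and bars for the mean and SD of 4 arrays. TMO7 lies near -2.05 on day 3 and -1.95 on day 6, where its Q0990 x bdl signal did not exceed the blank spots, while WOX5 lies at -1.98 on day 3 and 0.25 on day 6.

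Over all genes, limma called 8032 of 19087 on day 3, 4028 higher and 4004 lower. Most changes were small: 1257 of the calls reached 1.5-fold (713 higher, 544 lower) and 201 reached 2-fold (139 higher, 62 lower). The count was 5168 of 9973 tested genes with reporters above the blank spots in all 16 signals, and 5243 with day 3 fitted alone. With an estimated correlation the calls held on day 3 for the MONOPTEROS, shoot apex, endosperm, seed coat, cell cycle and photosynthesis lists, and in the Q0990 x Col-0 comparison below for photosynthesis, seed maturation and seed coat. None held on day 6 or for the difference between days.

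On day 6, the largest falls included ASL5, which had also fallen on day 3, and the largest rise was that of the myrosinase gene TGG1. ASL5 was 5.13-fold lower (log2 -2.36 ± 0.720 SD, adjusted p = 2.01e-04). Its Q0990 x bdl signal exceeded the blank spots on 2 of 4 arrays, and 1 array stood at -1.28. The sugar transporter gene SWEET9 was at least 4.66-fold lower (adjusted p = 4.89e-06), since its Q0990 x bdl signal did not exceed the blank spots on any array. AT5G35940, a jacalin lectin gene measured on day 6 only, was at least 3.46-fold lower for the same reason (adjusted p = 4.89e-05). AT1G35290, a thioesterase family gene, was 7.23-fold lower (log2 -2.85 ± 0.0998 SD, adjusted p = 3.54e-07). AT2G30560, a glycine-rich protein gene, was 6.24-fold lower (log2 -2.64) and AT3G13857 6.18-fold lower (log2 -2.63). XTH15, a xyloglucan-modifying enzyme gene, was 5.11-fold lower (log2 -2.35), with 1 of 4 Q0990 x bdl signals above the blank spots, and AT2G20515 was 4.46-fold lower (log2 -2.16).

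TGG1 was 6.35-fold higher on day 6 (log2 2.67 ± 0.247 SD, adjusted p = 3.56e-06). HSD1, a steroleosin gene of oil bodies, was 5.43-fold higher (log2 2.44 ± 0.279 SD, adjusted p = 1.23e-04). The Q0990 x Col-0 signal exceeded the blank spots on 2 of 4 arrays for TGG1 and on 1 for HSD1. The tonoplast aquaporin gene GAMMA-TIP was 3.19-fold higher (log2 1.67 ± 0.0371 SD), the storage globulin gene CRA1 3.16-fold (log2 1.66), the cell wall protein gene CWLP 2.99-fold (log2 1.58) and the cystatin gene CYS2 2.79-fold (log2 1.48). AT4G22450 was 3.56-fold higher (log2 1.83 ± 0.684 SD). AT1G22330, which encodes an RNA recognition motif protein, was 2.79-fold higher (log2 1.48 ± 0.573 SD, adjusted p = 0.00784). Its call ended without an offset, and its Q0990 x Col-0 signal exceeded the blank spots on 1 of 4 arrays. These 16 rises and falls kept 1 sign on 4 of 4 arrays.

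On day 6, 6 of 15 MONOPTEROS targets and vascular initiation genes fell and 2 rose (6 and 3 adjusted over the list alone). The list did not pass (median -0.11, also with 2 members at their bounds, camera adjusted p = 0.167). LOG3 fell 2.68-fold (log2 -1.42 ± 0.0532 SD, adjusted p = 4.91e-06). TMO7 was at least 2.57-fold lower (adjusted p = 4.79e-05), since its Q0990 x bdl signal exceeded the blank spots on no array. LOG4 fell 1.94-fold (log2 -0.95) and SOK1 1.85-fold (log2 -0.89). Of 21 Aux/IAA genes, 6 fell and 3 rose, the same adjusted over the list alone (camera adjusted p = 0.450). IAA19 was 2.60-fold lower and IAA27 1.43-fold higher. Of 8 root pole genes, 4 fell and 1 rose, the same adjusted over the list alone (camera adjusted p = 0.195). They included PLT1, 4.07-fold lower (log2 -2.03 ± 0.344 SD) with 1 of 4 Q0990 x bdl signals above the blank spots, and the root cap gene FEZ, 1.41-fold lower.

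Of 21 seed maturation and storage genes, 12 rose and 1 fell on day 6, the same adjusted over the list alone (median 0.29, camera adjusted p = 2.37e-05 over the 19 measured on both days, but adjusted p = 0.0707 with an estimated correlation). SESA4 was 2.03-fold higher and the oleosin gene OLEO1 1.98-fold. Of 35 photosynthesis genes, 18 rose and 1 fell (19 and 1 adjusted over the list alone; median 0.24, camera adjusted p = 2.37e-05, but adjusted p = 0.0874 with an estimated correlation), with PSAD2 1.44-fold and PSBQ2 1.41-fold higher. Of 15 shoot apex and cotyledon genes, 10 rose and 2 fell, the same adjusted over the list alone (median 0.28, camera adjusted p = 0.0284 over the 13 measured on both days, but adjusted p = 0.189 with an estimated correlation). Its members moved apart: the leaf growth regulator TCP4 was 2.00-fold higher and the meristem gene KNAT1, measured on day 6 only and so not in the list test, 3.29-fold lower (log2 -1.72 ± 0.170 SD). With the dye orientation read from the values, this list no longer passed.

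The markers of other seed tissues did not pass on day 6. Endosperm genes had 3 of 13 higher and none lower, the same adjusted over the list alone (median 0.025, camera adjusted p = 0.320). Seed coat genes had 4 of 25 higher and 4 lower (3 and 4 adjusted over the list alone; median 0.011, camera adjusted p = 0.716). Other lists also did not pass, tested like all lists over the members measured on both days. Auxin transport and synthesis genes had 9 of 20 lower and 3 higher (camera adjusted p = 0.0536), cytokinin response genes 7 of 16 lower and 3 higher (camera adjusted p = 0.320), epidermis genes 6 of 14 higher and 1 lower (camera adjusted p = 0.128), and vascular tissue genes 2 of 13 higher and 2 lower (camera adjusted p = 0.978). Of these 4 lists each count was the same adjusted over the list alone. Cell cycle genes had 8 of 36 higher and 3 lower (7 and 3 adjusted over the list alone; camera adjusted p = 0.128). Ground tissue genes had 3 of 8 lower and 1 higher (camera adjusted p = 0.320), auxin response factors 4 of 15 lower and 2 higher (camera adjusted p = 0.395), and the suspensor and zygote list 1 of 4 higher (camera adjusted p = 0.659), the same adjusted over the list alone. GH3 and LBD genes had 3 of 9 lower and 1 higher (4 and 1 adjusted over the list alone; camera adjusted p = 0.716). Touch and wounding genes had 3 of 10 lower (2 adjusted over the list alone; camera adjusted p = 0.395). Heat shock genes had 1 of 5 higher and none lower (1 and 1 adjusted over the list alone; camera adjusted p = 0.659).

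**Figure D2:**
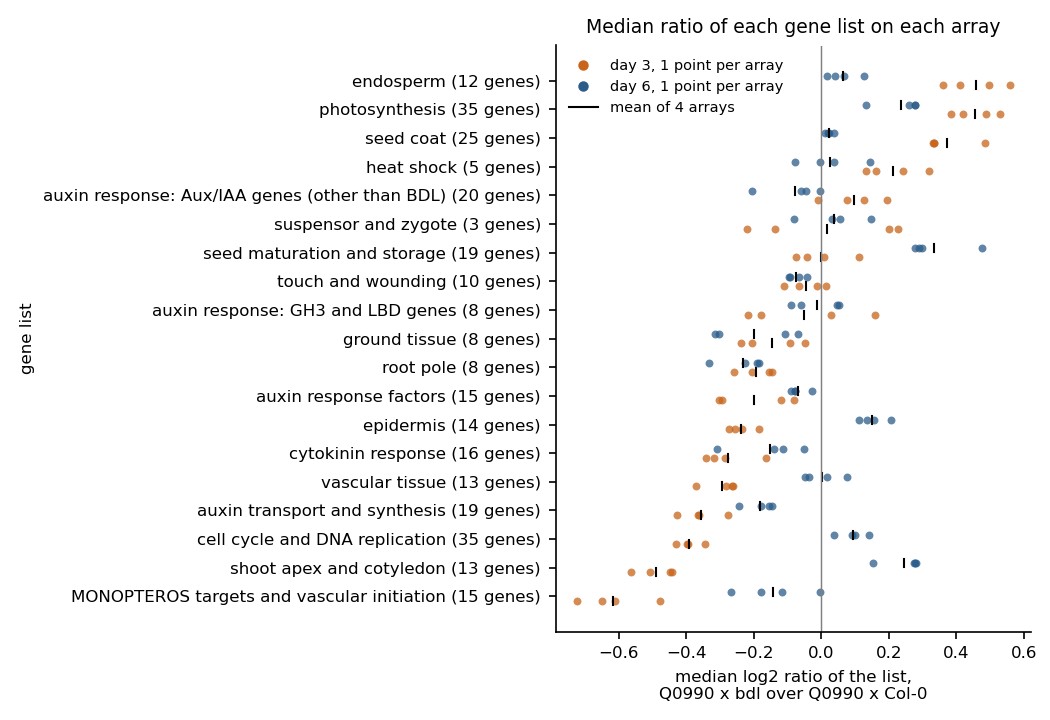
Median log2 ratio of Q0990 x bdl over Q0990 x Col-0 (horizontal axis) of each of the 19 gene lists (vertical axis), with 1 point per array for day 3 and day 6 and a line at the mean of 4 arrays, over the members measured on all 8 arrays. The MONOPTEROS targets and vascular initiation list lies between -0.722 and -0.478 on the day 3 arrays, and the endosperm list between 0.361 and 0.558.

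Over all genes, 6939 of 19467 were called on day 6, 3163 higher and 3776 lower. Of these, 1027 reached 1.5-fold (196 higher, 831 lower) and 260 reached 2-fold (27 higher, 233 lower), so that the larger changes were mostly falls. The count was 4545 without day 6 replicate 1 and 4507 without day 6 replicate 3.

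The effect of the cross differed between the days for many genes. WOX5 differed by 2.23 (log2, day 6 effect minus day 3 effect, adjusted p = 1.35e-05): it was lower on day 3, and on day 6 its ratio was 0.25 (adjusted p = 0.0422), with 1 of 4 signals of either cross above the blank spots. The cotyledon boundary gene CUC1 was lower on day 3 and higher on day 6, a difference of 1.80 (adjusted p = 1.24e-04). AT4G22450, above the blank spots on 1 of 4 day 3 arrays in either cross, differed by 1.83, AT1G29270 by 1.77, CWLP by 1.72 and the xyloglucan-modifying enzyme gene XTH9 by 1.71. The largest differences downward were genes higher on day 3 and lower on day 6: AT1G53285 (-4.002, adjusted p = 1.51e-06), the lipid transfer protein family gene AT1G43667 (-3.58), AT1G35290 (-3.55), AT5G05030 (-3.39) and AT1G21395 (-3.33). SESA3 differed by -3.31, higher on both days.

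Of the lists, 7 differed between days with the preset correlation and none with an estimated one. Shoot apex and cotyledon genes rose relative to day 3 in 11 of 13 cases with none lower (11 and 1 adjusted over the list alone; median 0.84, camera adjusted p = 1.34e-05, but adjusted p = 0.0636 with an estimated correlation). Cell cycle genes did so in 22 of 35 cases with 1 lower (24 and 1 adjusted over the list alone; median 0.43, camera adjusted p = 4.95e-07, but adjusted p = 0.0636 with an estimated correlation). MONOPTEROS targets and vascular initiation genes were relatively higher in 8 of 15 cases with 1 lower (median 0.23, camera adjusted p = 0.0158, but adjusted p = 0.238 with an estimated correlation). Epidermis genes were so in 8 of 14 cases with 2 lower (median 0.29, camera adjusted p = 0.0362, but adjusted p = 0.165 with an estimated correlation). The counts of these 2 lists were the same adjusted over the list alone. Seed maturation genes were relatively higher in 8 of 19 cases with 3 lower (9 and 3 adjusted over the list alone, median 0.17, camera adjusted p = 0.0362, but adjusted p = 0.165 with an estimated correlation). Seed coat genes were relatively lower in 11 of 25 cases with 1 higher, the same adjusted over the list alone (median -0.34, camera adjusted p = 0.00593, but adjusted p = 0.107 with an estimated correlation). Photosynthesis genes were relatively lower in 14 of 35 with 3 higher (16 and 4 adjusted over the list alone, median -0.25, camera adjusted p = 0.0362, but adjusted p = 0.230 with an estimated correlation). Without background correction, the calls of the epidermis, seed maturation and photosynthesis lists ended. Those of the MONOPTEROS and photosynthesis lists ended with scaling between arrays.

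**Figure D3:**
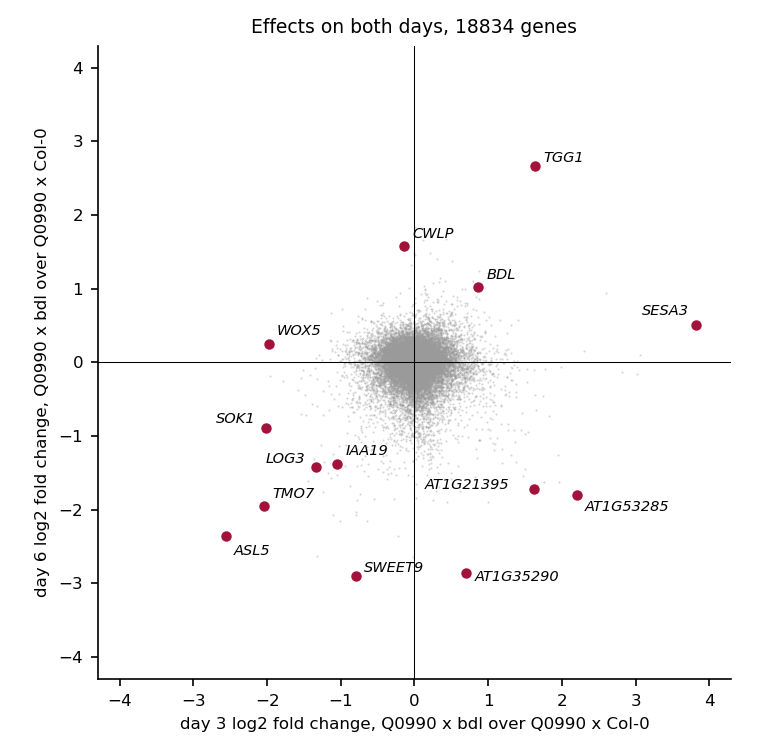
Fitted log2 fold change of Q0990 x bdl over Q0990 x Col-0 on day 3 (horizontal axis) against day 6 (vertical axis), with 1 grey point for each of 18834 genes and some named genes in red. ASL5, TMO7, LOG3 and IAA19 lie in the lower left corner, and the cloud as a whole has no slope (Pearson r = 0.0154 across genes).

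Across the 18834 genes measured on both days, the effects were nearly uncorrelated (Pearson r = 0.0154, Spearman rho = -0.00777, across genes, which are not independent replicates). limma called 7769 genes for the difference, 3668 upward and 4101 downward. Of these, 2480 differed by at least 1.5-fold (873 upward, 1607 downward) and 593 by at least 2-fold (129 upward, 464 downward). Genes called higher on both days numbered 822 against 636 for independent lists, and genes lower on both days 866 against 778. Opposite calls were also above that number, 851 against 772 for higher then lower and 808 against 641 for lower then higher. At 2-fold or more, 17 genes were lower on both days, 1 was higher on both (TGG1) and 18 went opposite ways. Besides ASL5, TMO7, LOG3, AT3G13857 and AT2G20515, the 17 included IAA19 and NPY4, a gene of the family that acts with PID. NPY4 was singled out here after its value was seen.

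Between day 3 and day 6, seed maturation and photosynthesis transcripts rose in the Q0990 x Col-0 samples, while transcripts of the seed coat list fell. AT1G62220 rose by 8.50 (log2, 95% interval 7.42 to 9.58, adjusted p = 4.20e-09), AT1G09750, an aspartyl protease gene, by 7.40, AT3G01570, an oleosin gene, by 6.87 and the oleosin gene OLEO4 by 6.68. The sugar transporter gene SWEET11 rose by 6.24 and SESA2 by 6.08. On day 3, SWEET11 exceeded the blank spots on 1 of 4 arrays, and AT1G62220, AT1G09750 and SESA2 on 3. The largest falls were of genes not above the blank spots on any day 6 array. They were AT1G10190 (at least 301-fold lower, adjusted p = 5.83e-10), the expansin gene EXPA21 (at least 263-fold lower, adjusted p = 6.67e-12), the small cysteine-rich protein genes SCRL10 (at least 212-fold lower, adjusted p = 1.54e-12) and LCR24 (at least 184-fold lower, adjusted p = 1.11e-11), and AT2G02490 (at least 190-fold lower, adjusted p = 8.88e-14). MLP328 was 371-fold lower (log2 -8.54), with 1 of 4 day 6 arrays above the blank spots. BDL did not pass, at 0.71 (95% interval 0.147 to 1.26, adjusted p = 0.0590). It passed in 4 of the alternatives, among them the omission of day 3 replicate 2.

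Of 35 photosynthesis genes, 26 rose and 1 fell in Q0990 x Col-0 (27 and 1 adjusted over the list alone; median 1.61, camera adjusted p = 1.51e-12, and adjusted p = 0.00647 with an estimated correlation). PSAO rose by 3.08 and PSBO2 by 2.89. Of 19 seed maturation and storage genes, 11 rose and none fell (11 and 1 adjusted over the list alone; median 0.94, camera adjusted p = 1.97e-06, and adjusted p = 0.0185 with an estimated correlation), among them SESA3 by 4.91. Of 25 seed coat genes, 14 fell and 1 rose (15 and 2 adjusted over the list alone; median -1.57, camera adjusted p = 2.14e-07, and adjusted p = 0.0185 with an estimated correlation). The MADS gene STK was 29.6-fold lower and SHP1 at least 20.103-fold lower. Of 12 endosperm genes, 4 fell and none rose (5 adjusted over the list alone; median -0.73, or -0.67 with 2 members at their bounds, camera adjusted p = 0.00489, but adjusted p = 0.0858 with an estimated correlation). PHE1 was 8.92-fold lower and AGL36 at least 2.08-fold lower. Of the suspensor and zygote list, 2 of 3 fell, the same adjusted over the list alone (median -0.83, camera adjusted p = 0.0476, but adjusted p = 0.202 with an estimated correlation). SSP was 3.31-fold lower and WOX8 1.77-fold lower, each above the blank spots on 1 of 4 day 6 arrays. This list's call ended with 7 of the 8 arrays left out singly, all but day 3 replicate 1.

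**Figure D4:**
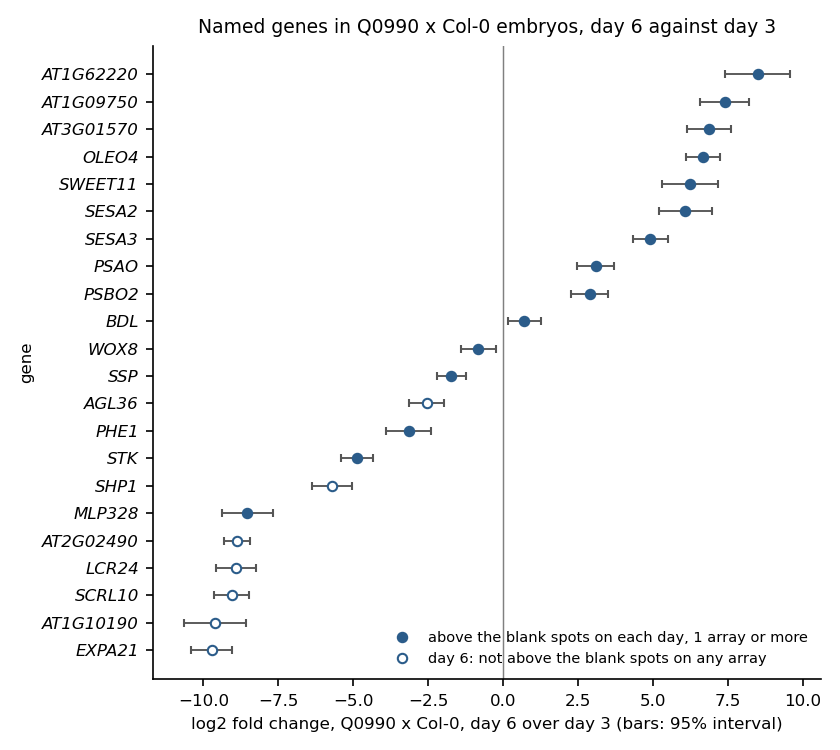
Fitted log2 fold change of day 6 over day 3 (horizontal axis) in Q0990 x Col-0 for the named genes (vertical axis), with bars for the 95% interval of the fit. Open points are genes not above the blank spots on any day 6 array, for which only a bound holds, such as EXPA21 at least 263-fold lower.

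The separate-channel fit called 4951 of 18817 genes between the days, 2507 higher and 2444 lower on day 6, and 3691 of them changed at least 2-fold. With the strict filter the count was 2421. Each array held 1 day only, so any difference between the day 3 and day 6 hybridizations is part of this comparison. So is any change in the share of other seed tissue, whose markers fell between the days (medians -1.57 for seed coat, -0.73 for endosperm). Whether that share changed was not tested. The spots of the print control plate had median Col channel intensities of 1697 on day 3 and 533 on day 6.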

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

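The 7769 genes and the lists that differ between days come from tests fixed before the files were seen, as do the chance splits. All tests that weigh the 3 patterns at the end were chosen after the result was seen, and the rules of 7 (embryo share, normalization, younger stage, older stage, dye labels as given, endosperm and seed coat on day 6) were also made stricter after their values were seen.

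Of 109 groups of 4 arrays, 9 had an array far from the other 3, where chance gives about 1 in 20. Among genes on day 6, GAMMA-TIP stood at 1.728 on replicate 3 against 1.652 to 1.656, and ASL5 at -1.28 on replicate 1 against -2.743 to -2.699. On day 3, PHV stood at -0.6523 and PLT2 at -0.2909 on replicate 1, against -0.7931 to -0.7694 and -0.7851 to -0.7497. AGL36 stood at 0.7214 on day 3 replicate 3 against 0.9635 to 0.9988. Among list medians on day 6, shoot apex and cotyledon stood at 0.1541 on replicate 3, seed maturation and storage at 0.4752 on replicate 2 and photosynthesis at 0.1323 on replicate 1. On day 3 the seed coat median was 0.4849 on replicate 4 against 0.332 to 0.3346.

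The effect of the cross differed between days for 7769 genes by the test of the difference. As list medians, the difference (day 6 effect minus day 3 effect) was 0.837 for shoot apex and cotyledon and 0.432 for cell cycle and DNA replication. It was 0.287 for epidermis, 0.225 for MONOPTEROS targets and vascular initiation, and 0.167 for seed maturation. For seed coat it was -0.341 and for photosynthesis -0.250. None of these 7 list calls held with an estimated correlation (adjusted p = 0.0636 to 0.238 with an estimated correlation). Of the named genes, these were relatively higher on day 6: WOX5 by 2.229, CUC1 by 1.798, FIL by 1.475, CUC3 by 1.418, YUC4 by 1.308, RGF8 by 1.2, PDF1 by 1.131, SOK1 by 1.125, AUR1 by 1.098, TCP4 by 1.08, CYCA1;1 by 1.023, DOF5.8 by 0.946, IAA30 by 0.830, PID by 0.7501, PHV by 0.65, ARR3 by 0.45 and IAA27 by 0.325. So did AT4G22450 by 1.826, AT1G29270 by 1.766, CWLP by 1.719, XTH9 by 1.707, AT1G22330 by 1.488, CYS2 by 1.268, GAMMA-TIP by 1.251, TGG1 by 1.036, SAG13 by 0.844 and OLEO1 by 0.835.

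Relatively lower on day 6 were TT7 (-0.46), ZOU (-0.57), HDG2 (-0.58), FEZ (-0.64), RBCS2B (-0.863), AHP6 (-1.096), AT2G20515 (-1.14), PLT1 (-1.237), AT3G13857 (-1.298), SESA2 (-1.665) and XTH15 (-2.135). Further down were AT1G62060 (-2.138), AT2G30560 (-2.62), AT1G62080 (-2.964), AT1G62000 (-3.176), SESA3 (-3.314), AT1G21395 (-3.33), AT5G05030 (-3.392), AT1G35290 (-3.553), AT1G43667 (-3.578) and AT1G53285 (-4.002). Of the genes above, WOX5 and RGF8 on day 6 and AT4G22450 on day 3 exceeded the blank spots on 1 of 4 arrays in either cross, and AT1G22330, CUC3, ZOU, AUR1 (Q0990 x Col-0), XTH15 and PLT1 (Q0990 x bdl) on 1 of 4 day 6 arrays in 1 cross, so the sizes of their differences are uncertain. For 5 more genes the fitted difference is not a measured size. SWEET9 (-2.101) and AT1G62210 (-2.949) had no Q0990 x bdl signal above the blank spots on day 6, and at their bounds the differences were -1.42 and -2.22. Neither cross exceeded the blank spots on day 6 for ZW9 (1.541) and AGL36 (-0.943), nor on day 3 for CRA1 (1.541).

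Signals outside the comparisons were found in control spots and microRNA reporters. Of the microRNA reporters, 33 exceeded the blank spots, and the same models called 5 of 33 on day 3 and 8 of 31 on day 6. Spots of the print control plate had Col channel medians of 1697 on day 3 and 533.3 on day 6. Alien control spots, which match no plant transcript, had medians of 45.63 and 255.0, against 9.294 to 25.07 and 12.17 to 18.97 for blank spots. These controls differ by day, as the hybridizations do, which limits the Q0990 x Col-0 comparison.

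Chance was tested by relabelling the arrays. The real signs called 8032 genes on day 3, against at most 3 for any other of the 8 sign swaps, and 6939 on day 6, against 0; 1 of 8 swaps reached the real count each time, and 8 splits are too few for a verdict. Of the 35 splits of the 8 arrays into 4 and 4, 1 reached the real counts of 7769 for the difference and 4951 for Q0990 x Col-0, with 0 called in any other. Every other split mixes the days, so a difference between days widens its spread, and the 0 does not measure false calls. The rank of 1 in 35 argues against chance for the grouping by day as a whole. It says nothing of single genes, and a batch that follows the day would give the same rank.

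The day 3 pattern was the fall of the MONOPTEROS targets and vascular initiation list beside the rise of endosperm and seed coat markers. A smaller share of embryo RNA stays open for the fall. The list that fell lay below the 6 other embryo lists together (difference -0.437, 95% interval -0.675 to -0.00482). Against each of these alone, 4 of 6 intervals held 0, as for shoot apex (difference -0.232, 95% interval -0.543 to 0.441). A larger share of other seed tissue in the Q0990 x bdl samples could account for the marker rise, since endosperm and seed coat both rose (medians 0.57 and 0.48). Their difference was 0.0936, but its 95% interval of -0.389 to 0.501 is too wide to show that they rose alike. Normalization stays open: the markers' median was 0.444 or more in 4 settings, but these moved genes by a median of at most 0.0192 and so did not test it. A younger stage remained undecided (mean r = -0.0922 across genes), and lists went both ways. Endosperm and seed coat, higher here, fell with age in Q0990 x Col-0 (medians -0.73 and -1.57), as a younger stage would give. Photosynthesis, also higher here (median 0.46), rose with age (median 1.61), as a younger stage would not give. The same holds for several of the largest single rises on day 3. SESA3 rose with age too, as did SESA2 by 6.08, AT1G62000 by 5.91, AT1G62080 by 4.55 and AT1G62060 by 4.25. AT1G62210, another of them, fell with age (-2.52). The seed maturation list as a whole had a median of 0.01 on day 3. A biological difference between the crosses in these tissues stays open and untested.

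The arrays also carried an opposite dye pattern within 1 label orientation. Dye labels of some arrays that differ from the labelling used could account for this: with the orientation read from overfull spots, deviations correlated 0.206 for the same and -0.205 for the opposite orientation (difference 0.410, 16 pairs across days). By the labels as given the difference was 0.00588, but this is no separate test and leaves them open: the reading departs from the labels on 2 of 4 arrays of each day, so a value near 0 follows from the first. Either way each day has both orientations in equal number. No biological explanation was tested.

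On day 6 the pattern was the rise of seed maturation genes. An older stage of the Q0990 x bdl samples stays open: across all genes their effects barely followed the change with age in Q0990 x Col-0 (mean r = 0.0277), but photosynthesis and seed maturation, the 2 lists called in both, rose in both (medians of 0.24 and 0.29 on day 6, 1.61 and 0.94 with age). Neither day 6 call held with an estimated correlation (adjusted p = 0.0874 for photosynthesis and adjusted p = 0.0707 for seed maturation), while both calls with age did. Lists that fell with age showed no fall on day 6: seed coat stood at -1.57 with age and 0.011 on day 6, endosperm at -0.73 and 0.025, suspensor and zygote at -0.83 and 0.08. Only 14 of 25 seed coat and 3 of 13 endosperm genes exceeded the blank spots on every day 6 array. For SSP and WOX8 of the suspensor list, 1 of 4 Q0990 x Col-0 signals did. A further fall could hardly be seen in the endosperm and suspensor lists. It could be seen in the 14 seed coat genes, whose median on day 6 was 0.0047. The change of these 14 genes with age was not examined apart from their list. Seed coat and endosperm genes also mark other seed tissues. These lists therefore do not decide for or against an older stage. Over genes above the blank spots on every day 6 array, the 14 seed coat markers had a median of 0.0047, below the maturation genes (difference 0.498, 95% interval 0.105 to 0.932). For these markers this argues against a larger share of seed coat as the whole cause of the rise. The interval is over genes, not arrays, and a larger share as part of the cause was not tested. A larger share of endosperm stays open with 3 such markers (difference 0.492, 95% interval -0.0601 to 0.927). A biological difference between the crosses stays open and untested.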

How the results depend on the processing

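The reruns covered the named genes and lists that were called, and BDL, and none of these reversed its direction. Since nearly all were called at the start, few could gain a call. Lists that were not called were not part of this count. For some of them camera and fry gave opposite directions, such as vascular tissue on day 6. Among all called genes the sign turned with the brightest probe per gene for 1 on day 3, 7 on day 6 and 4 of the difference, and with the strict filter for 1 each on day 6 and of the difference. Of 7071 reruns for 317 results on named genes, 6765 kept the call, 300 lost it and 6 gained it, and of 390 reruns for 25 list results 356 kept and 34 lost it. On day 3 the count of 8032 became 5168 with the strict filter (9973 genes tested), 5243 with each day fitted alone and 1257 with a 1.5-fold threshold added. With that threshold day 6 gave 1027 and the difference 2480, and in Q0990 x Col-0 the strict filter gave 2421; both settings call fewer genes by construction. With arrays left out singly, the counts were 6491 to 7889 on day 3, 6178 to 7447 for the difference and 3378 to 4995 in Q0990 x Col-0. On day 6 they were 4507 (without day 6 replicate 3) to 7063 (without day 3 replicate 4). BDL stayed between 0.83 and 0.91 on day 3 and between 0.97 and 1.06 on day 6. Lists past the threshold numbered 10 on day 3, 3 on day 6, 7 for the difference and 5 in Q0990 x Col-0; with an estimated correlation 6, 0, 0 and 3, and with fry 17, 14, 13 and 14. Without background correction the difference kept 4 lists. For the difference, the estimated correlation lay below the preset 0.01 for shoot apex (-0.0335), seed maturation (-0.0226), epidermis (-0.0052) and seed coat (0.0039). A higher correlation among members therefore does not account for the loss of these calls. The estimate lay above the preset for cell cycle (0.0323), photosynthesis (0.0232) and the MONOPTEROS list (0.102). The cause of the list changes was not otherwise tested. The dye orientation read from the values gave 9847, 9138, 9686 and 4855 genes. A replicate block had a correlation of -0.284, with 8168, 7143, 6446 and 4626 genes. Deviations of arrays with the same number correlated -0.213, -0.183, -0.146 and -0.259 across days. Read from the values, arrays with the same number had opposite dye orientations on the 2 days. All pairs of opposite orientation correlated -0.205 on average, so these values cannot tell whether equal numbers pair. Not run were a slide or scan block, as none is given, the series table for single genes and lists, as it has no gene names, and each day alone for Q0990 x Col-0. Signal over the blank spots limits the genes for which only a bound is given.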

Other observations

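Gene families read from the array's gene descriptions were tested too; these 16 families were chosen after the data were seen, and some of their members also stand in the fixed lists. On day 3, 3 of the 16 passed. Of 211 cytosolic ribosomal protein genes, 87 fell and 3 rose in Q0990 x bdl (median -0.14, camera adjusted p = 1.25e-06, and adjusted p = 0.00410 with an estimated correlation). Of 48 histone genes, 29 fell and 1 rose (median -0.31, camera adjusted p = 2.80e-07, and adjusted p = 0.025 with an estimated correlation). Of 60 MADS box genes, among them AGL36 of the endosperm list, 29 rose and 5 fell (median 0.20, camera adjusted p = 8.09e-04, but adjusted p = 0.121 with an estimated correlation). The endosperm and seed coat lists had medians of 0.57 and 0.48 on the same arrays. On day 6, 32 of 80 lipid transfer protein genes fell and 8 rose (median -0.17, camera adjusted p = 0.00369), as did 10 and 2 of 30 expansin genes (median -0.15, camera adjusted p = 0.0232). Neither held (adjusted p = 0.162 with an estimated correlation for both).

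The effect differed between days for 5 families, beside list differences of -0.34 for seed coat and -0.43 for endosperm genes (the latter did not pass, camera adjusted p = 0.0624). Ribosomal protein genes were relatively higher on day 6 in 78 of 210 cases and lower in 20 (median 0.18, camera adjusted p = 1.36e-04, and adjusted p = 0.0104 with an estimated correlation). Histones (median 0.27), MADS box genes (median -0.32), lipid transfer protein genes (median -0.24) and kinesins (median 0.18, camera adjusted p = 0.0231) passed only with the preset correlation (adjusted p = 0.0580 for the first 3 and adjusted p = 0.208 for kinesins with an estimated correlation). In Q0990 x Col-0 between the days, where the seed coat and endosperm lists had medians of -1.57 and -0.73, 8 of 14 oleosin genes rose and none fell (median 1.45, camera adjusted p = 2.99e-06). Ribosomal protein genes had 49 of 210 lower and 6 higher (median -0.37, camera adjusted p = 2.23e-05), MADS box genes 16 of 59 lower and 4 higher (median -0.32, camera adjusted p = 6.32e-04) and histones 11 of 46 lower and none higher (median -0.28, camera adjusted p = 0.00331). None of these 4 held (adjusted p = 0.207 for histones and adjusted p = 0.0672 for the others with an estimated correlation).

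On chromosome 1, 5 genes with close codes, picked after the values were seen, rose together on day 3. AT1G62000, AT1G62060, AT1G62080, AT1G62210 and AT1G62220 rose by 3.02, 2.30, 3.06, 2.82 and 1.99. On day 6 their values were -0.16, 0.16, 0.10, -0.13 and -0.07, none of which passed. In Q0990 x Col-0 between the days, AT1G62210 fell (-2.52), while the other 4 rose by 5.91, 4.25, 4.55 and 8.50. Of 12 measured genes between them, 6 also passed on day 3, with smaller values in both directions, from -0.62 for APR2 to 0.64 for AT1G62030.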
